A study of Mus musculus with 8 samples.

How the data were processed

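Total RNA from livers was isolated with a Qiagen lipid tissue kit and made into ribosomal RNA-depleted, stranded Illumina libraries, per the labels' protocols. The labels also give the cell type as hepatocyte, while the series description speaks of dissected livers. There were 8 libraries, 4 per serum group, assigned from the sample titles. Per the submitters' processing notes the tools were FastQC 0.12.1, STAR 2.7.11b, featureCounts and Subread 2.0.3, and the genome build was GRCm38. The annotation and the strand setting are not given in the sources used here.

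The file used holds 1 row per gene name. Per the file headers, the authors deposited a mean of normalized counts over all libraries, treated here as a non-negative signal. The authors also deposited a log2 fold change with its standard error on the log2 scale. A test statistic, here called a score, was deposited by the authors, and the deposited p-value and adjusted p-value follow it. These headers are those of DESeq2 results, per the file headers, and the tool's version is not given in the sources used here. The statistic equalled fold change over standard error within 2.58e-14 and the p-value a two-sided normal p within 2.89e-15. Benjamini-Hochberg adjustment over the 6227 rows with an adjusted p gave the deposited values within a relative difference of 6.91e-13. The lowest level with an adjusted p was 27.7 normalized counts, the 8019 rows without one lay at or below 27.7 or had no p-value, and 13 rows had a level of 0. Because the table holds no counts per library, the quasi-likelihood test, normalizations, clustering and leave-one-out fits planned before the data were examined could not be computed, and the authors' own test is reported in their place. Depth per library is unknown, so precision is given only as the authors' standard error, with a median of 0.174 on the log2 scale over rows with an adjusted p.

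Row names were matched to GENCODE M21 on GRCm38: 13094 of 14246 names were found, 13076 of them unique. The displacement of levels from names was estimated with a hidden Markov model along each chromosome. For each row the logarithm of coding exon length overlapped by the row's exons was computed in 20 bp bins at 4001 displacements, in steps of 500 bp up to 1000 kb to either side, and set against the normal score of the row's level. The prior chance of a new displacement at each row was 0.02 and the prior share of no displacement 0.5. A row was placed at its own position when the posterior of a displacement within 1 kb of none was at least 0.95. A row was placed at a displaced position when that posterior was at most 0.05 and its displacement was determined within 2 kb with a posterior of at least 0.95. No coordinate was converted between builds. On levels simulated for the 13040 rows with the fitted displacements, 97.6% of 850 rows placed at their own position were right. So were 97.5% of 6761 rows placed as displaced. Right means within 2 kb of the simulated displacement, a wider limit than the 1 kb that defines a row's own position. These shares do not show that each row counted the gene of its name. On levels simulated without displacement, 12475 of 13040 rows were placed at their own position and 0 as displaced.

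Genes were named by a rule fixed before the data were examined: Khdc3; per sign the 12 genes with the largest absolute log2 fold change past an adjusted p of 0.05 with a mean of at least 1 CPM, leaving out predicted, Rik and pseudogene names; up to 4 members of lists with a call or with at least 2 members past the threshold; and the smallest p to fill up to 10 per sign. The rule's demand that groups not overlap could not be checked, and the rule was applied to rows at their own position. Its part on lists took members past the threshold by label, none of them at its own position. The 35 gene lists were fixed before the data were examined and were tested with cameraPR in limma 3.58.1 (R 4.3.3) on the deposited statistic, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment. In 50 sets of simulated statistics on the 6227 rows, 98.5% of lists shifted by 2.5 with a spread of 1.3 and 1.26% of other lists were called. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Alternatives were other filters, gene classes, posteriors, correlations and ranks. Overlapping genes are uncertain throughout, because levels over coding exons of the opposite strand were as high as over those of the same strand.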

Results

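Livers of female mice were profiled by total RNA sequencing at 1 month of age, to ask whether serum given to a mother before mating left a mark on the liver transcriptome of her daughters. The mothers were wild-type females injected intraperitoneally with pooled serum, 200 µl every 12 h for 3 injections and 600 µl in total, and were mated with a wild-type male 24 h later. The serum came from wild-type females of wild-type ancestry (WT serum) or from wild-type females whose ancestors lacked Khdc3 (WT* serum), a gene of the oocyte and early embryo. Each serum group had 4 libraries. The sample titles speak of injected females and the series description of their offspring, and the series description was followed here. It states 2 injected females, and litters are not labelled. With 4 libraries per group, some daughters in each group must share a mother, whether 2 is meant per group or in all. The mother was the treated unit, so the effect of serum cannot be separated from that of mother and litter. The p-values measure only the spread between these samples.

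The data analysed here were the authors' deposited table of 1 comparison between the 2 serum groups, with no value per library, so the depth of each library is unknown. The authors' deposited table has 14246 rows, of which 6227 carry an adjusted p, and its mean levels sum to 7596370 normalized counts. Which serum group is the numerator of the fold changes is not stated, so changes are given as positive or negative and not as higher or lower in a group. For the same reason no value per group, no standard deviation and no grouping of libraries is given.

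In the authors' deposited table the row labelled Khdc3 had a mean level of 0.73 normalized counts, a log2 fold change of -0.0025 ± 1.92 (SE) and no adjusted p. This row could not be placed by the fit described next, so its level cannot be read as that of Khdc3. All libraries came from genetically wild-type mice, so it would not check the labels either.

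The names of most nuclear rows could not be read as the genes counted. In the authors' deposited table, some rows named for abundant transcripts were low: Alb, the serum albumin gene, had a mean of 72.1 normalized counts, Apoe, an apolipoprotein gene, 5.77, and Actb, cytoplasmic actin, 1.69. Other names were high, such as Kng1, a kininogen made by liver, at 258415 in the authors' deposited table, and the 8 rows named for hepatocyte markers had a median of 433.6. Some rows named for genes outside liver physiology were high too in the authors' deposited table, with 129276 for Dsg3, a desmosomal cadherin of skin, and 22622 for Vmn1r185, a vomeronasal receptor. A fit along each chromosome of the GRCm38 assembly asked at which distance from the named gene the levels followed coding exons. Of 13040 rows in the fit, 646 followed coding exons at their own position, 6322 followed exons at a displaced position and 6072 could not be placed. The median displacement was -109.5 kb on chromosome 11, -164 kb on chromosome 10, -23.5 kb on chromosome 6 and 726.5 kb on chromosome 8. In a further fit every other row was left out. Of the rows left out, the 1849 whose neighbours gave a determined displacement away from the named position were used. Their Spearman correlation across rows between level and coding overlap was 0.464 at the displacement of their neighbours, against 0.206 at no displacement. Rows are not independent replicates, and these correlations describe this table only.

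**Figure D1:**
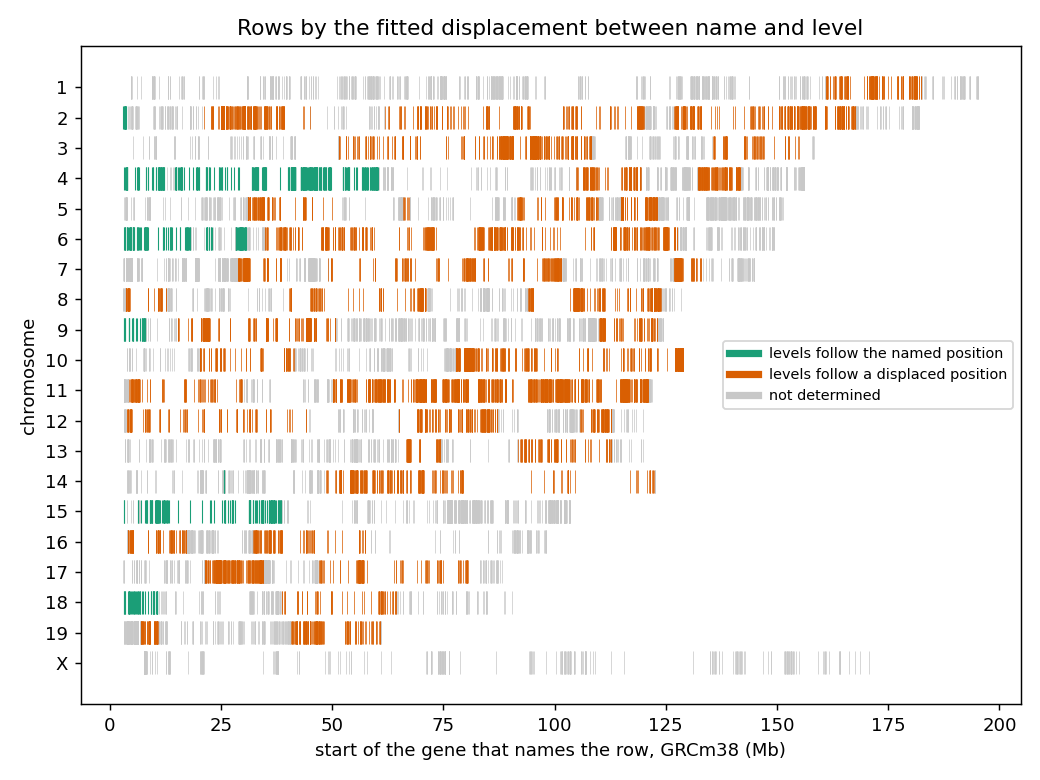
Map of the 13040 rows in the fit, each a line at the GRCm38 start (Mb) of the gene that names it on chromosomes 1 to 19 and X. Green lines are the 646 rows whose levels followed their named position, orange lines the 6322 rows that followed a displaced position and grey lines the 6072 rows not placed; green is found mainly at the start of chromosomes 4, 6, 9, 15 and 18.

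Rows at their own position lay mainly on chromosome 4 from 3.24 to 60.2 Mb (324 rows), chromosome 6 from 3.34 to 30.7 Mb (109 rows), chromosome 15 from 3.28 to 38.5 Mb (133 rows), chromosome 18 from 3.27 to 10.8 Mb (41 rows) and chromosome 9 from 3.19 to 8.00 Mb (26 rows). Several genes abundant in liver were high there. In the authors' deposited table Mup7, a major urinary protein, had a mean of 63035 normalized counts, Pon1, the paraoxonase carried on lipoproteins, 39307, and Baat, which conjugates bile acids, 11342. Ribosomal protein genes there were uneven in the authors' deposited table, with 3801 for Rps20 and 39.7 for Rpl30. Genes are therefore named as genes only for these rows and for the mitochondrial genome, and any other row is called by its label. Mitochondrial rows were not in the fit, so their names are used as deposited and were not tested.

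Between the serum groups, 240 rows of the authors' deposited table had an adjusted p under 0.05 (Wald test with Benjamini-Hochberg adjustment), 146 positive and 94 negative. By size, 39 of these rows changed at least 2-fold, 21 positive and 18 negative, and the median absolute log2 fold change of the 240 rows was 0.61. At an unadjusted p under 0.05 (Wald test) there were 1279 of all 14229 rows with a p-value, including those without an adjusted p. Of the 240 rows, 31 were at their own position, 106 displaced, 86 not placed and 17 without a unique name in the reference annotation. Rows with an adjusted p in these classes numbered 425, 2850, 2505 and 424. The called share was thus highest at their own position, where the median level was highest too. Median levels over all rows of the classes were 166, 19.5, 15.0 and 9.98 normalized counts. None of the 33 mitochondrial rows passed, and 23 of them had an adjusted p. Among called rows that cannot be read as their names, the largest fold changes in the authors' deposited table belonged to those labelled Zbtb16 (-3.39), Gm5600 (-3.12), Myh9 (2.62) and Rbm15 (2.54), as log2 values.

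Of the 31 called genes at their own position in the authors' deposited table, 22 were positive and 9 negative. Dnaja1, a co-chaperone of cytosolic HSP70 at chromosome 4, 40722150 to 40737149, had the smallest adjusted p of this set in the authors' deposited table, with a log2 fold change of 0.69 ± 0.12 (SE, adjusted p = 1.09e-06). Dnajb5, another HSP40 family co-chaperone, had 0.44 ± 0.12 in the authors' deposited table, and Cct5, a subunit of the cytosolic chaperonin, 0.26 ± 0.07. Erp44, which retains client proteins in the early secretory pathway, changed by 0.29 ± 0.08 and Calu, a calcium-binding protein of the secretory pathway, by 0.35 ± 0.11 in the authors' deposited table. Calu had an adjusted p of 0.0360, above the 0.0357 of Map3k8, a gene that did not pass with no low-level filter. Calu therefore does not pass with no filter either. Dnaja1 was the only member of the fixed heat shock list at its own position. Dnajb5, Cct5, Erp44 and Calu were outside the naming rule and were chosen after their values were seen. They were not tested as a set, and Tmem38b, a channel of the endoplasmic reticulum, was called with a negative sign. Exons of Dnaja1 share sequence positions with those of Smu1, so reads of the 2 genes can be mixed.

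The other positive genes were of mixed function. Among called genes at their own position, Osgin2 had the largest positive log2 fold change in the authors' deposited table, 0.98 ± 0.22 (adjusted p = 0.0011). Col15a1, a basement membrane collagen, followed with 0.88 ± 0.16 (adjusted p = 2.61e-05) and Ccne2, cyclin E2 of the G1 to S transition, with 0.87 ± 0.25 (adjusted p = 0.019) in the authors' deposited table. Log2 fold changes in the authors' deposited table were 0.86 for Ica1, 0.64 for Polr1e, a subunit of RNA polymerase I, and 0.54 for Snrpd1, a core protein of the spliceosome. Signalling and innate immune genes were Map3k8 (0.56), Ripk2 (0.47) and Samd9l (0.48), an interferon-inducible gene, again as log2 fold changes in the authors' deposited table. Nans, which makes sialic acid, had 0.50 and Snd1 0.46 in the authors' deposited table. Ccne2 shares exon positions with Ints8 and Nans with Trim14. Ica1 and Map3k8 did not pass with no low-level filter (adjusted p of 0.085 and 0.077).

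The called negative genes at their own position were led by Pdk4, the kinase that inactivates pyruvate dehydrogenase and is induced by fasting. Its log2 fold change in the authors' deposited table was -1.69 ± 0.48 (SE, adjusted p = 0.016). Fbxo10, an F-box protein, had -1.10 ± 0.23 (adjusted p = 0.000251) and Pnrc1, a nuclear receptor coactivator, -0.77 ± 0.19 (adjusted p = 0.0042) in the authors' deposited table. Smaller negative log2 fold changes in the authors' deposited table belonged to Slc44a1, a choline transporter (-0.51), Ppp1r9a (-0.47), Zfp622 (-0.38), Xpa, a nucleotide excision repair protein (-0.38), Tmem106b, a lysosomal membrane protein (-0.38), and Tmem38b (-0.29). With 9 negative genes past the threshold, Tox was added by the naming rule and did not pass, at -0.64 ± 0.21 and an adjusted p of 0.057 in the authors' deposited table. Xpa shares exon positions with Ncbp1. Xpa and Zfp622 did not pass with no low-level filter (adjusted p of 0.097 and 0.080).

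**Figure D2:**
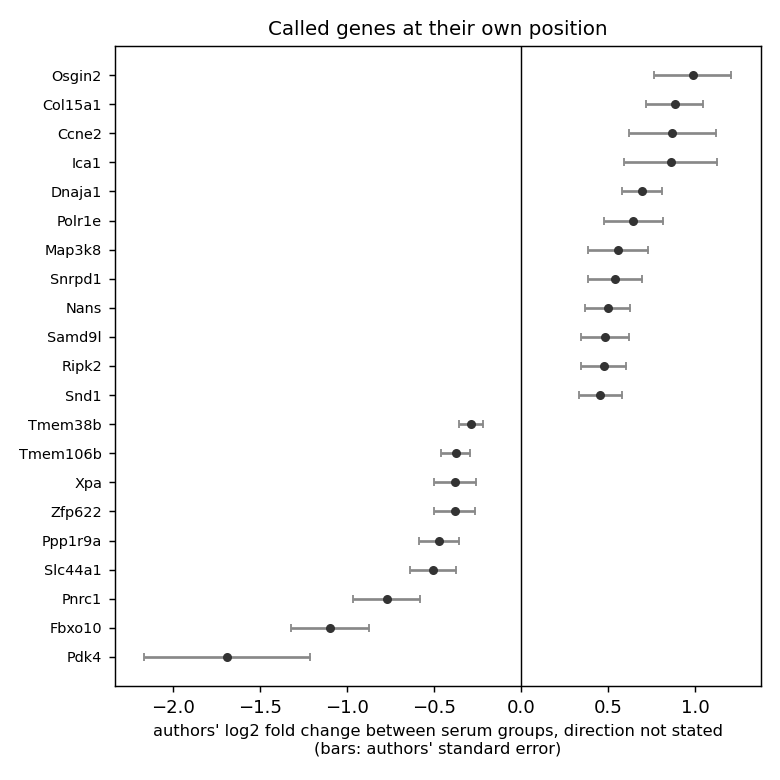
Authors' log2 fold change between the serum groups (horizontal axis, direction not stated) for 21 genes past the threshold at their own position; points are fold changes and bars the authors' standard errors. The range runs from Pdk4 at -1.69 to Osgin2 at 0.98.

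Of the genes in the 35 fixed lists, 29 were at their own position, 26 had an adjusted p and 3 passed, namely Dnaja1, Ccne2 and Pdk4. Listed genes of liver metabolism at their own position other than Pdk4 did not pass. In the authors' deposited table the log2 fold change was -0.30 ± 0.65 for Cyp7a1, the rate-limiting enzyme of bile acid synthesis, and 0.11 ± 0.10 for Baat. It was 0.15 ± 0.09 for Decr1 of fatty acid oxidation and 0.24 ± 0.09 for Abca1, the cholesterol exporter. Outside the lists, Coq3 of ubiquinone synthesis passed at its own position, with 0.35 ± 0.11 (adjusted p = 0.032) in the authors' deposited table. With no low-level filter 23 genes at their own position passed, and by the order of adjusted p Coq3 was not among them. The growth hormone receptor Ghr had -0.19 ± 0.09 and the imprinted gene Mest -0.48 ± 0.21 in the authors' deposited table, with adjusted p of 0.21 and 0.20. Mup7, a male-biased urinary protein gene, had -0.41 ± 0.18 (adjusted p = 0.20) in the authors' deposited table, and reads of the near-identical Mup genes cannot be told apart with certainty.

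The mitochondrial list did not pass as a set, with members of both signs. Of 15 listed mitochondrial rows, 12 had an adjusted p in the authors' deposited table, 4 had an unadjusted p under 0.05 and 0 passed, and their camera test gave p = 0.70 (adjusted p = 0.88). The smallest adjusted p of a listed mitochondrial row in the authors' deposited table was 0.071, for the large ribosomal RNA mt-Rnr2 (-0.37 ± 0.13). Its partner mt-Rnr1 had -0.29 ± 0.15 in the authors' deposited table, while mt-Nd5 had 0.17 ± 0.07, mt-Nd6 0.24 ± 0.09 and mt-Co1 0.0017 ± 0.079. The libraries were depleted of ribosomal RNA, and the part of depletion in the mt-Rnr1 and mt-Rnr2 values was not tested.

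Read by deposited names, 0 of 23 fixed lists with at least 5 rows passed the camera test, and 3 had an unadjusted p under 0.05. The smallest adjusted p was 0.052, for sinusoidal endothelial markers. Most rows of the nuclear lists lie where names and levels part, so these lists cannot be read as their genes. The mitochondrial list was read by its names, which the fit did not test, and some of its rows were far below the others. By label, 2 rows of the bile acid list passed in the authors' deposited table, Cyp8b1 (0.80 ± 0.19) and Slc51b (-1.49 ± 0.44), and 3 adjusted over the list alone. The sinusoidal endothelial list also had 2, Stab2 (0.87 ± 0.18) and Fcgr2b (0.52 ± 0.15) in the authors' deposited table, and 3 adjusted over the list alone. None of these 4 rows was at its own position. An estimated correlation needs values per library and was not computed.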

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

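No paired analysis was possible because the deposited table holds no value per library. For the same reason DESeq2 and voom refits, other normalizations, leaving out mitochondrial and abundant genes before scaling, the surrogate variable, leave-one-out fits, fry, the estimated correlation and the clustering of libraries were not run. Alternatives chosen only after the data were seen were the level minimum of 100, the limits to rows at their own position, the posteriors, the correlations of 0 and 0.05, ranks, and assignment by covered gene. The 240 called rows were 194 with no low-level filter, 187 without predicted, Rik and pseudogene names and 269 at a level of at least 100. Limited to rows at their own position and mitochondrial rows they were 40, and those at least 2-fold were 2 in place of 39, since fewer rows were tested (448). The 31 called genes at their own position ranged from 23 with no filter to 41 when adjusted over these rows alone. Lists called went from 0 to 1 at a preset correlation of 0, where the smallest adjusted p was 0.039, and stayed at 0 at 0.05 and with ranks. By covered gene 2 lists were called, and 1, lipogenesis, when each row counted only for the gene it covers most, since the endoplasmic reticulum stress list then had under 5 rows. With ranks the latter list by covered gene did not pass (adjusted p = 0.073). Of 87 alternative values for the 22 named genes, 81 kept their side of the threshold. With no filter Ica1 (0.085), Map3k8 (0.077), Xpa (0.097) and Zfp622 (0.080) no longer passed, and Tox passed in 2 alternatives (0.040 and 0.032). Without depth per library, no limit from counting can be given.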

Other observations

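The tests of shuffled levels, of opposite-strand counting, of wrong displacements and of clock genes were chosen after the results were seen, as was the reading of rows by the genes they cover. Read by the coding gene covered at the fitted displacement (at least 100 bp), rows over the fixed endoplasmic reticulum stress list had the smallest camera p of 17 lists tested. For each gene only the row covering most of it was used. The list has 26 members, and 11 displaced rows were assigned to them, of which 7 had an adjusted p and were tested. These 7 rows, 5 of them positive, had a median log2 fold change of 0.71 in the authors' deposited table and a camera adjusted p of 7.52e-06. The call was lost when ranks replaced the statistic (adjusted p = 0.073), and the list had too few rows to be tested when each row counted only for the gene it covers most. Hyou1, a chaperone of the endoplasmic reticulum, lay under 3 called rows with log2 fold changes of 1.84, 1.78 and 1.69 in the authors' deposited table, of which the row used had 1.84 ± 0.36 (SE). The row over Hspa5, which encodes BiP, had 1.35 ± 0.30, the row over Hsp90b1 0.87 ± 0.18 and the row over Pdia4, a disulfide isomerase, 0.71 ± 0.16 in the authors' deposited table. The rows used are labelled C030014I23Rik, Cutal, Stab2 and Zfp786, and the ones over Hspa5 and Hsp90b1 cover only 156 and 104 bp of those genes and more of a neighbour. Displacements were tried in steps of 500 bp and determined only within 2 kb. Overlaps this short therefore do not settle which gene a row covers. The rows over Xbp1, Ddit3 and Chac1 cover only 348, 141 and 408 bp of those genes. Of the 7 tested rows, only those over Hyou1 and Pdia4 cover more than the 500 bp step, with 1886 and 902 bp. The list test thus rests mostly on rows whose gene is not settled. Rows over Xbp1 (0.40), Ddit3 (-0.07) and Chac1 (-0.35) did not pass in the authors' deposited table. Asns, the only list member at its own position, had -0.16 ± 0.33 there and no adjusted p.

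The lipogenesis list was the other call by covered gene, with 7 of 8 rows positive and an adjusted p of 0.0019, and it passed with ranks (adjusted p = 0.018) and when each row counted only for the gene it covers most (adjusted p = 0.0029). Only the row over Acly, which makes cytosolic acetyl-CoA, passed by itself, with a log2 fold change of 0.60 ± 0.18 in the authors' deposited table. The rows over Acly and Acaca cover 312 and 326 bp of those genes, also less than the 500 bp step of the fit. The rows over Fasn (0.44), Acaca (0.65) and Gpam (0.42) did not pass, and the row over Scd1 was negative (-0.22) in the authors' deposited table.

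The mismatch between names and levels may come from gene coordinates of another genome build laid over reads aligned to GRCm38, which is a hypothesis, since no other build was used here. It needs levels that follow exons at a shared displacement. Rows left out of the fit whose neighbours were placed as displaced had a rank correlation of 0.464 with coding overlap at their neighbours' displacement. Shuffling argues against names that were merely mixed up: the highest of 10 shuffled sets placed 15 rows and the real levels 6968. Over all 13040 rows in the fit, level had a rank correlation of 0.027 with opposite-strand coding overlap at the named position. With same-strand overlap it was 0.220. The low value argues only weakly against counting on the wrong strand there. Rows without opposite-strand overlap are tied, and how many have any was not counted. At the fitted displacement the median level was 39.7 normalized counts over same-strand exons, 37.3 over opposite-strand exons and 2.96 over no coding exon, so the counting may not have used strand.

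The positive shift of rows over endoplasmic reticulum stress genes may reflect a difference in protein folding load between the livers compared, as a hypothesis found and tested on the same data and resting on 4 called rows. Of these rows, those over Hspa5 and Hsp90b1 were assigned by overlaps shorter than the 500 bp step of the fit. So were the tested rows of the list that were not called. For this list, 2 of 342 wrong displacements with at least 3 rows gave a mean statistic as high as 2.88, with a highest value of 3.75. Of 10000 sets matched on level, 0 did (0%). These values argue against chance assignment to distant genes and against high levels alone. The wrong displacements were all far larger than 2 kb. They therefore cannot test whether a row covers a listed gene or its neighbour, and that stays open. Over all fixed lists with at least 5 rows, 0 of 2422 list tests in 903 wrong displacements (0%) lay as far from the mean, at most 3.85 standardized against 5.19, though a wrong displacement had a median of 2 such lists and the fitted one 13. Clock phase or feeding time at collection cannot be told apart from the serum, because only 3 clock genes lay under a row with an adjusted p, while negative Pdk4 (-1.69 in the authors' deposited table), which fasting induces, and the positive lipogenesis list go the way a feeding difference would. Serum, litter and handling also stay open and untested, and which group would be the higher is not stated.

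Some mitochondrial messenger rows were far below the others in the authors' deposited table, such as mt-Co2 at 33.8, mt-Co3 at 38.5 and mt-Atp6 at 28.1 normalized counts against 1181640 for mt-Co1. Sequence shared with nuclear copies is a candidate explanation. Over 13 protein-coding rows, the rank correlation between level and the share of 50-base words found in transcripts of nuclear genes was -0.476, between the bounds set beforehand. The shares were 100% for mt-Co2, 99.9% for mt-Co3, 99.5% for mt-Atp6, 98.8% for mt-Nd4l and 98.0% for mt-Nd3. In the authors' deposited table mt-Nd4l and mt-Nd3 were low too, at 4.13 and 4.21. The next highest share was 62.2%, for mt-Nd4 at 174516 normalized counts, and mt-Co1 had 51.1%. The exception was mt-Atp8, with a share of 0% and a low level of 6.73 in the authors' deposited table. Only annotated transcripts of nuclear genes were searched, so its 0% cannot exclude a nuclear copy elsewhere. The explanation stays open, and no biological explanation was tested.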
